A study of Mus musculus with 8 samples.

How the data were processed

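Gene expression was measured on 8 arrays hybridised with amplified, biotin-labelled cDNA from mouse CJ7 embryonic stem cells, in 4 groups of 2 arrays. Per the labels, cells were exposed to concentrated lentivirus for 24 hours with polybrene at 2.5 mcg/mL, selected with puromycin at 2 mcg/mL and harvested 48 hours after infection. The labels call the arrays of a group biological replicates but do not say how the cultures were separated, so p-values measure the spread between these arrays, part of which may be technical. Each array's group and replicate number came from its title and was never inferred from its values.

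The deposited values are intensities on a linear scale, 1 per probe set and array. RMA, which corrects background, equalises the probe distributions between arrays and summarises the probes of a set, is named in the submitters' processing notes with no version stated. The whole-series table also holds a present, marginal or absent call per probe set and array; the method behind the calls is not given in the sources used here. The authors' 3 deposited tables of intensity held identical values, with 0 values that differed. Intensities ran from 9.71 to 34525 over all arrays, and the array medians from 141 to 149.8. The share of probe sets called present ran from 62.1% to 66.5%.

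The tables hold 45101 probe sets, of which 64 are array controls and were left out. GEO's platform annotation gave exactly 1 gene symbol for 34958 probe sets, several symbols for 932 and no entry for 9211, which are unnamed here. Updating symbols through the Entrez identifier changed 0 of them. Probe sets called present on at least 2 of the 8 arrays were kept (31554), and 26080 of these had 1 symbol. Each gene was represented by its probe set with the highest mean log2 intensity over all arrays, which left 14027 genes. The deposited columns had been normalized by RMA and differed little in their medians, so log2 was taken with no further normalization and no pseudocount. Where a gene was called present on no array of the dimmer group and on at least 1 of the brighter group, the fold is given as a bound ("at least"). The bound is the bright group's mean over the dim group's mean of, per array, the higher of the measured value and the lowest intensity called present. For Olr1 and Mmp12 in Sall4b-only against control cells the bound equalled the measured fold (28.6 and 8.28). Their measured values lay above that lowest intensity, so "at least" rests there on the absent calls alone.

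Analyses used R 4.3.3 with limma 3.58.1 and statmod 1.5.0. A linear model of 4 group means was fitted to all 8 arrays with lmFit and eBayes, which left 4 residual degrees of freedom and 6.20 after moderation. All 8 arrays shared a variance estimate because 4 arrays alone leave few degrees of freedom. The 6 comparisons were each group against control, each add-back group against the depleted group, and the add-back groups against each other. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Means are given on the log2 scale with the SD of 2 arrays, and log2 differences with the standard error (SE) of the fit.

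For gene groups, 24 lists were written: pluripotency, trophoblast, primitive endoderm, epiblast, mesoderm and primitive streak, neuroectoderm, Hox genes, germ cell, 2-cell-like, fibroblast and feeder, interferon response, p53 response, cell cycle G2/M, Wnt targets, FGF/ERK targets, BMP targets, LIF/STAT3 targets, NuRD complex, Polycomb complex, SALL family, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and amino acid response, and imprinted genes. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 144 tests of 24 lists and 6 comparisons. The same test with a correlation estimated per list stands beside it. In camera, a list is compared with the other genes. In fry, added after the data were seen, its genes are tested for moving, on balance, in 1 direction.

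The groups, tests, filters, lists, the rule for named genes and most of the alternative settings below were fixed before the data were examined. Named genes are Sall4, the 8 largest rises and falls past the threshold without overlap between the arrays of the groups (5 in the comparisons against the depleted group), and up to 4 members of each list with the smallest p. Where fewer than 5 genes passed in a direction, those that passed and the 5 with the smallest p were named as not passing. Symbols of clones and predicted genes were passed over. Pou5f1, Nanog, Sox2, Klf4, Esrrb, Cdx2, Eomes, Gata4, Gata6, Sox17, Fgf5 and T are always named for depletion where measured. Some of the other list members past the threshold over their list alone are also named, a choice made after the values were seen. Remaining genes named outside the rule are marked as chosen after their values were seen.

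The gene test was checked on 20 simulated data sets of the depleted and control comparison with 14027 genes, 200 of them changed. It called 45.5% of genes changed 2-fold, 82.0% of those changed 4-fold and 91.9% of those changed 8-fold, with a mean of 8.55 false calls. In 20 simulations of Sall4a-only against Sall4b-only with the trophoblast list shifted by 0.5 log2, camera called that list in 20 runs at the preset correlation and in 12 at the estimated correlation. It called 0 of 420 unshifted lists. Simulated genes varied independently, and the adjustment ran over the 24 lists of a single comparison. These runs therefore do not give the rate of false calls for lists of correlated genes. They also gave all groups the same spread per gene. In the data the SD of the replicate difference was 0.27 log2 in depleted, 0.41 in control and 0.62 in Sall4a-only cells. The simulated shares of changed genes called therefore need not hold for these arrays. In the real data the estimated correlation was 0.87 for fibroblast markers and 0.70 for G2/M genes, against the preset 0.01.

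Alternative settings chosen at that time were no detection filter, presence on all 8 arrays, cyclic loess, the other deposited table, the mean of a gene's probe sets, every probe set, a trended and robust prior, only the 2 groups compared, the replicate number as a block, an added 1.5-fold threshold, an estimated correlation and leaving out each array. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the other groups. Alternatives chosen after seeing the data were the fit without both Sall4a-only arrays, a crossed block, fry, and a set of genes at an unadjusted p under 0.01. Probe sequences and their positions in the Sall4 transcripts were not used here.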

Results

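Arrays measured gene expression in CJ7 cells, a line of mouse embryonic stem (ES) cells. Per the labels, the zinc-finger transcription factor Sall4 was depleted, and a cDNA of either isoform, Sall4a or Sall4b, was added back in some groups. The 8 arrays form 4 groups of 2. Control cells carried a lentivirus with no short hairpin RNA (shRNA), and depleted cells carried an shRNA against both isoforms. Sall4a-only and Sall4b-only cells carried the shRNA together with a cDNA of the named isoform that the shRNA does not target. RNA was collected 48 hours after infection. With 2 arrays a group, the number of arrays limits the precision, and an exact two-sided permutation test of 2 against 2 cannot give a p below 0.333.

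Replicates of the Sall4a-only group lay further apart than those of the other groups. The SD over genes of the difference between replicates was 0.62 log2 in Sall4a-only cells, against 0.41 in control, 0.27 in depleted and 0.28 in Sall4b-only cells. In Sall4a-only cells, 1160 genes differed by over 1 log2 between the replicates, against 420, 100 and 133 in the other groups in that order. Markers of fibroblasts and feeder cells averaged -1.86 log2 against the control mean on Sall4a-only replicate 1 and 0.22 on replicate 2. Genes of the 2-cell-like state averaged -1.03 and 1.05 on the same arrays. Over all genes the Sall4a-only arrays correlated at 0.968 with each other and more closely with every array of the other groups: replicate 1 most with Sall4b-only replicate 1 (0.983) and replicate 2 most with depleted replicate 2 (0.985). A mean of the Sall4a-only group is therefore a mean of unlike arrays. Control arrays (0.9857) also each correlated more closely with the depleted array of the same number (0.9898 and 0.987).

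The Sall4 transcript itself was read by a brighter and a dimmer probe set. The brighter had a mean intensity of 14427 ± 918 (SD, n = 2) in control cells, 10411 ± 111 in depleted, 9092 ± 68.5 in Sall4a-only and 9745 ± 252 in Sall4b-only cells. The dimmer had 348 ± 20.1 in control, 147 ± 13.3 in depleted, 155 ± 4.18 in Sall4a-only and 177 ± 47.8 in Sall4b-only cells. In depleted against control cells the log2 difference was -0.47 (SE 0.11) for the brighter and -1.25 (SE 0.20) for the dimmer probe set, lower on both depleted arrays than on either control array. Neither passed limma over the 31554 probe sets, with adjusted p = 0.463 and 0.370. Against depleted cells the dimmer probe set differed by 0.086 log2 in Sall4a-only and 0.25 in Sall4b-only cells (SE 0.20), and the brighter by -0.20 and -0.096 (SE 0.11), and none of these passed. Against control the brighter probe set differed by -0.66 in Sall4a-only and -0.56 in Sall4b-only cells (SE 0.11); with a trended and robust prior Sall4 passed there among genes (adjusted p = 0.0402 and 0.0379), but not in depleted cells (adjusted p = 0.157). Probe positions were not used here, so whether these probe sets could read an added cDNA or tell the isoforms apart is not known. The arrays therefore do not show the return of either isoform, and a weak or failed add-back stays open. In depleted cells Sall4 RNA was 1.38-fold lower by the brighter and 2.37-fold lower by the dimmer probe set, a partial fall. The group names give the intended state, and incomplete depletion stays open too.

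**Figure D1:**
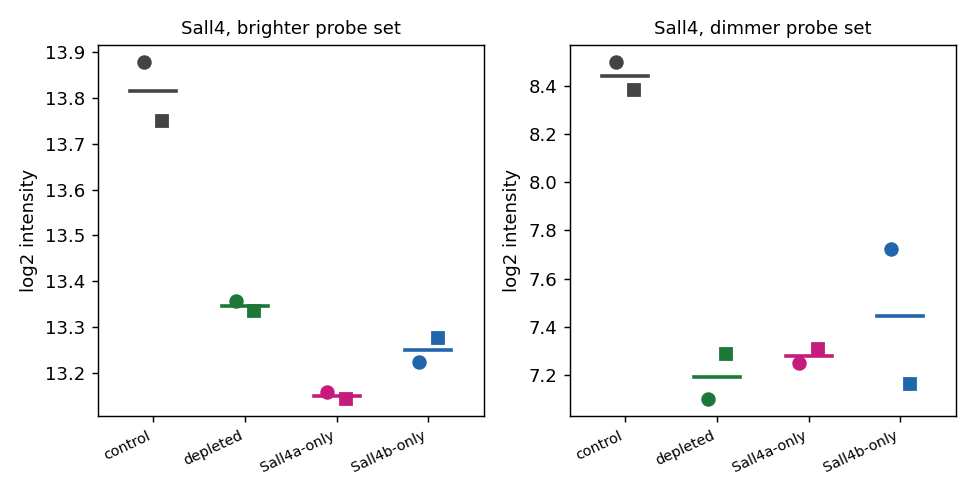
Log2 intensity of the brighter (left) and dimmer (right) Sall4 probe set on each array, by group; circles are replicate 1, squares are replicate 2 and bars are group means. Control arrays lie highest in both panels, and the vertical axes differ in range.

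Depletion of both isoforms was compared with the control to ask which genes depend on Sall4. The control virus carried no shRNA. In each comparison with control, an effect of lower Sall4 therefore cannot be told apart from one of carrying an shRNA. Of the core pluripotency factors, Pou5f1 differed by 0.13 log2 (SE 0.20), Nanog by -0.027 (SE 0.13), Sox2 by 0.15 (SE 0.22), Klf4 by -0.28 (SE 0.31) and Esrrb by -0.034 (SE 0.32). Among genes with the smallest p, the purinergic receptor gene P2ry10b was 5.85-fold higher, at 7.02 ± 0.33 log2 (SD, n = 2) against 4.48 ± 0.0094. The proton pump gene Atp12a was 7.97-fold higher (9.03 ± 0.27 against 6.03 ± 0.32) and the prolactin family gene Prl3a1 5.83-fold higher (7.05 ± 0.43 against 4.51 ± 0.34). Prr32, called present on neither control array, was at least 4.03-fold higher. The matrix metalloproteinase gene Mmp12 was 3.95-fold lower (6.19 ± 0.11 against 8.17 ± 0.029). Their adjusted p were 0.139 for P2ry10b and Mmp12 and 0.180 for Atp12a, Prl3a1 and Prr32, so none passed.

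In depleted cells 5 lists passed at the preset correlation and 0 with an estimated correlation or by fry. The 24 measured G2/M cell cycle genes were all higher, by a mean of 0.28 log2 (camera adjusted p = 1.20e-04, but adjusted p = 0.956 with an estimated correlation); Nusap1 differed by 0.58 (SE 0.19) and Ccnb2 by 0.48 (SE 0.25). Pluripotency genes averaged 0.21 higher, with 29 of 40 members above control (adjusted p = 0.0017, and 0.956 with an estimated correlation), led by the Nodal antagonist genes Lefty1 (1.19, SE 0.28) and Lefty2 (0.91, SE 0.22) and by Tcea3 (0.85, SE 0.24) and Lin28a (1.00, SE 0.38). Trophoblast genes averaged -0.37, with 16 of 24 lower (adjusted p = 0.0011, and 0.956 with an estimated correlation). Within that list, 5 members passed when adjusted over the list alone and 0 over all genes: Esx1 (-1.06, SE 0.17), Plet1 (-1.05, SE 0.28), Dlx3 (-1.002, SE 0.21) and Tpbpa (-0.64, SE 0.16) were lower and Fgfr2 (0.90, SE 0.16) higher. Cdx2 and Eomes, regulators of early trophoblast, differed by 0.33 (SE 0.36) and 0.36 (SE 0.30).

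Genes of the unfolded protein and amino acid response averaged -0.28 in depleted cells, with 16 of 20 lower (adjusted p = 0.0045, and 0.956 with an estimated correlation). The stress-induced factor genes Atf3 and Ddit3 differed by -1.42 (SE 0.39) and -0.90 (SE 0.26), whereas Cth, which makes cysteine, differed by 1.22 (SE 0.20) and passed over the list alone. Fibroblast and feeder markers averaged 0.49 higher (21 of 24, adjusted p = 0.0137, and 0.956 with an estimated correlation), and they moved beside every group named here. Of primitive endoderm regulators, Gata4 differed by -0.83 (SE 0.39), Gata6 by -0.98 (SE 0.47) and Sox17 by -0.42 (SE 0.55); the list averaged -0.10 and did not pass (adjusted p = 0.641). The epiblast gene Fgf5 differed by -0.40 (SE 0.58). Pyruvate kinase (Pkm), in the glycolysis list, was 1.92-fold lower (12.6 ± 0.052 against 13.6 ± 0.068), past the threshold over the list alone (adjusted p = 0.0023).

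By limma, 0 of 14027 genes passed over all genes in depleted against control cells, with 1111 at an unadjusted p under 0.05 where 701 are expected by chance. The count was 0 with only the 2 groups in the fit and 2 (Pkm and P2ry10b) with a trended and robust prior. It was 1 (Tnfrsf11b) without depleted replicate 2, and 0 without any other array. No fit paired only the control and depleted arrays by their number, so the count under such a pairing is not known. Groups did not overlap at 41.1% of genes, against 33.3% by chance. Without control replicate 2 no list passed: the G2/M mean was 0.079 and the pluripotency mean -0.0198. Without control replicate 1 those means were 0.49 and 0.43, so the size of both rests on how the control arrays differ. The trophoblast mean was -0.22 without depleted replicate 1 and -0.27 without control replicate 2, the unfolded protein and amino acid response mean was -0.19 without control replicate 2, and the fibroblast mean was 0.63, 0.36 and 0.42 without control replicate 1, control replicate 2 and depleted replicate 1; none of these passed.

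Sall4a-only cells were compared with the control to ask what a state with Sall4a alone looks like. Mmp12 fell at least 8.99-fold, from 8.17 ± 0.029 log2 (SD, n = 2) in control to 5.01 ± 0.14 in Sall4a-only cells, where it was called present on neither array (log2 difference -3.17, SE 0.17, limma adjusted p = 0.0163). Short of the threshold, Dynap was at least 7.66-fold lower (adjusted p = 0.0703), the keratin gene Krt6a at least 7.15-fold lower (0.0773) and Krtap4-16 at least 5.26-fold lower (0.120). Proser2 was 6.23-fold higher (0.0887) and the transcription factor gene Klf12 2.43-fold higher (0.144). Of the fibroblast markers, Col5a2 was at 7.66 ± 0.72 against 10.8 ± 0.21, and Col3a1 at 7.10 ± 2.06 against 10.4 ± 0.55. The Mmp12 call was lost with only the 2 groups in the fit (adjusted p = 0.3805), with the replicate number as a block (adjusted p = 0.0554), and without either control array, either depleted array or Sall4a-only replicate 1.

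Primitive endoderm genes averaged -0.63 log2 in Sall4a-only against control cells, with 22 of 27 lower (camera adjusted p = 1.22e-06, and 0.956 with an estimated correlation). Members with the smallest p were the nuclear receptor gene Hnf4a (-1.43, SE 0.24), which passed over the list alone, Thbd (-2.33, SE 0.56), Gata6 (-1.76, SE 0.47) and Fst (-0.93, SE 0.28). Fibroblast markers averaged -0.82 on the same arrays (19 of 24 lower, adjusted p = 1.60e-04, and 0.956 with an estimated correlation), but that mean was 0.22 without Sall4a-only replicate 1 and -1.86 without replicate 2. The primitive endoderm mean was -0.37 and -0.88 in the same order and passed both times. Germ cell genes averaged -0.29 (14 of 20 lower, adjusted p = 0.0154, and 0.956 with an estimated correlation), with Asz1 at -2.10 (SE 0.53) and Dazl at -1.11 (SE 0.30). Unfolded protein and amino acid response genes averaged -0.24 (15 of 20 lower, adjusted p = 0.0037, and 0.956 with an estimated correlation), and G2/M genes 0.24 (23 of 24 higher, adjusted p = 0.0116, and 0.956 with an estimated correlation). The germ cell mean was -0.057 without Sall4a-only replicate 2 and -0.24 without control replicate 2, neither of which passed, and -0.53 without Sall4a-only replicate 1. The G2/M mean was 0.0435 without Sall4a-only replicate 1 and 0.038 without control replicate 2, neither of which passed, and 0.44 and 0.45 without the other array of each pair. Without control replicate 2 or Sall4a-only replicate 2 the unfolded protein and amino acid response mean was -0.14 and did not pass.

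Trophoblast genes as a list did not pass in Sall4a-only against control cells, with a mean of 0.091 and 13 of 24 higher (adjusted p = 0.960). Members went both ways, with 4 past the threshold over the list alone: Dlx3 (1.48, SE 0.21), Cdx2 (1.55, SE 0.36) and Fgfr2 (0.78, SE 0.16) were higher and Plac1 (-1.45, SE 0.33) lower. Lefty1 (1.66, SE 0.28) and Lefty2 (1.21, SE 0.22) were higher and passed over the pluripotency list alone. By limma 1 gene fell and 0 rose over all genes, with 1240 at an unadjusted p under 0.05, and 30.0% of genes did not overlap against 33.3% by chance. Without Sall4a-only replicate 2 the group is replicate 1 alone, the array that stood apart. Leading genes of that fit included Rian, Cd44 and Cav1, which lay lower on that array than on any other. Its count therefore describes that array rather than the group. No gene passed with either control array, either depleted array or Sall4a-only replicate 1 left out, while 110 passed without Sall4a-only replicate 2 (25 higher and 85 lower).

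Sall4b-only cells were compared with the control in the same way. Mmp12 fell at least 8.28-fold, to 5.12 ± 0.30 log2 (SD, n = 2; log2 difference -3.05, SE 0.17, limma adjusted p = 0.0206). At an adjusted p of 0.0504, just over the threshold, Olr1, a scavenger receptor gene, was at least 28.6-fold lower (4.84 ± 0.015 against 9.68 ± 0.27) and Dynap at least 6.41-fold lower. At the same adjusted p, the semaphorin gene Sema3d was 7.46-fold higher (8.56 ± 0.43 against 5.66 ± 0.16) and Klf12 3.24-fold higher. Krt6a was 6.48-fold lower (adjusted p = 0.0524). The Mmp12 call was lost without any of the control, depleted or Sall4b-only arrays, with adjusted p between 0.0747 and 0.293.

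Trophoblast genes were the group furthest below control in Sall4b-only cells, with a mean of -0.87 log2 and 19 of 24 members lower (camera adjusted p = 9.13e-08, and 0.956 with an estimated correlation). Over the list alone 9 members were lower and 1 higher. The keratin genes Krt19 and Krt7 were 7.11-fold and 6.18-fold lower, and Hand1, a regulator of trophoblast giant cells, was 6.72-fold lower. Plac1 was 3.98-fold lower, Rhox6 4.46-fold, Rhox9 3.77-fold, Plet1 2.87-fold, Gata2 2.51-fold and Esx1 2.23-fold lower, and Fgfr2 was 1.52-fold higher. The list mean lay between -0.97 and -0.77 whichever array was left out.

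Cell cycle G2/M genes averaged 0.53 higher in Sall4b-only than in control cells, all 24 of them higher (adjusted p = 2.07e-06, and 0.956 with an estimated correlation); Mki67 differed by 1.02 (SE 0.34), Nusap1 by 0.81 (SE 0.19) and Bub1 by 0.79 (SE 0.21). Pluripotency genes averaged 0.44, with 37 of 40 higher (adjusted p = 2.96e-05, and 0.956 with an estimated correlation), among them Gbx2 (1.74, SE 0.36), Lefty1 (1.25, SE 0.28), Lefty2 (1.10, SE 0.22) and L1td1 (0.59, SE 0.17). Fibroblast markers averaged -0.53 (17 of 24 lower, adjusted p = 0.0175, and 0.956 with an estimated correlation), with Lox at -3.13 (SE 1.08) and Col3a1 at -3.19 (SE 0.87). Interferon response genes averaged -0.32 (14 of 21 lower, adjusted p = 0.0175, and 0.956 with an estimated correlation), with Ifi35 (-1.57, SE 0.21) and Rsad2 (-1.29, SE 0.22) lower and Ddx58 (0.82, SE 0.18) higher past the threshold over the list alone. The p53 response list averaged -0.15 (adjusted p = 0.0443) and the unfolded protein and amino acid response list -0.22 (adjusted p = 0.0487), both with adjusted p = 0.956 with an estimated correlation; in the latter Atf3 (-2.02, SE 0.39), Ddit3 (-1.06, SE 0.26) and Sdf2l1 (-0.68, SE 0.18) were lower and Cth (1.19, SE 0.20) higher past the threshold over the list alone.

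The control arrays differed in several of these lists. In Sall4b-only against control cells the pluripotency mean was 0.22 without control replicate 2, where it did not pass, and 0.67 without control replicate 1, and the G2/M mean was 0.33 without control replicate 2 and passed. The fibroblast mean was -0.40 without control replicate 1 and -0.28 without Sall4b-only replicate 1, and the interferon response mean -0.32 and -0.245 without the same arrays; none of these passed. For the p53 response list the mean was -0.28 without control replicate 1, and it did not pass without control replicate 2 (-0.012), Sall4b-only replicate 1 (-0.11) or Sall4b-only replicate 2 (-0.18). The unfolded protein and amino acid response list did not pass without control replicate 2 (-0.13), Sall4b-only replicate 2 (-0.12) or either depleted array (-0.22).

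By limma 1 gene fell and 0 rose in Sall4b-only against control cells over all genes, with 2112 at an unadjusted p under 0.05, and 51.7% of genes did not overlap against 33.3% by chance. Without both Sall4a-only arrays in the fit, an alternative added after seeing the data, 52 genes rose and 69 fell. There Olr1 fell by 4.84 log2 (adjusted p = 0.0089), Sema3d rose by 2.90 (0.0171), Actc1, the cardiac actin gene, rose by 4.43 (0.0406) and the granzyme gene Gzme fell by 4.04 (0.0089). Trophoblast genes Krt7, Krt19, Hand1, Rhox6 and Rhox9 were among those that fell. So were the fibroblast markers Col3a1, S100a4 and Lox, while the fibroblast marker Cnn1 rose. Leaving out either Sall4a-only array gave the same count of 121, since a group left with 1 array adds nothing to the variance, and leaving out any other single array gave 0.

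**Figure D2:**
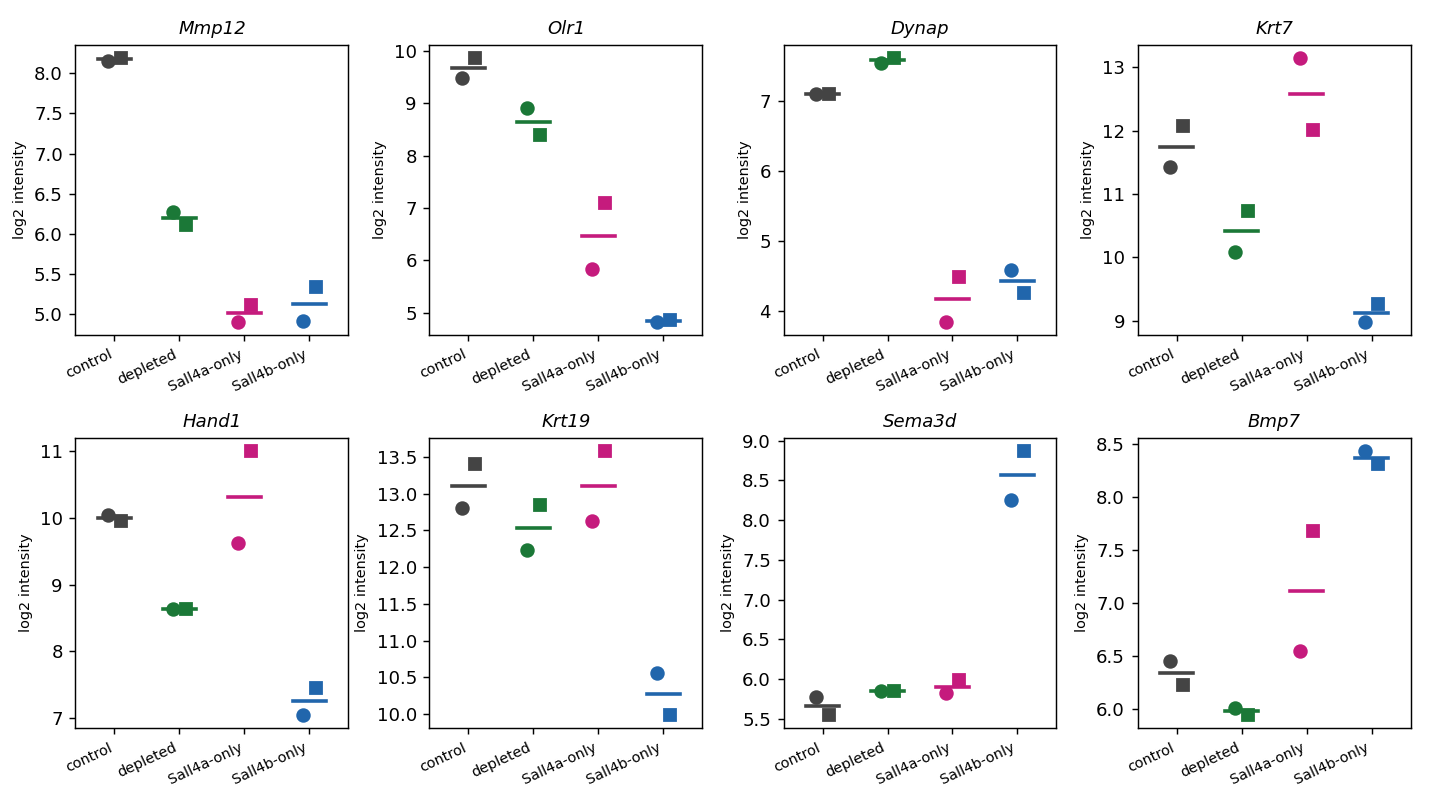
Log2 intensity of 8 genes on each array, by group; circles are replicate 1, squares are replicate 2 and bars are group means, and the vertical axes differ in range. Mmp12 lies lowest in both add-back groups, while Krt7, Hand1 and Krt19 lie lowest on the Sall4b-only arrays.

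Sall4a-only cells were set against the depleted cells, which carry the same shRNA but no added cDNA. In both comparisons with depleted cells, an effect of the isoform therefore cannot be told apart from one of carrying a cDNA construct. Trophoblast genes averaged 0.46 log2 higher with Sall4a (15 of 24 higher, adjusted p = 0.0116, and 0.956 with an estimated correlation), and 5 of them passed over the list alone: Dlx3 (2.49, SE 0.21), Krt7 (2.17, SE 0.43), Hand1 (1.68, SE 0.42), Wnt7b (1.55, SE 0.30) and Esx1 (1.22, SE 0.17). Fibroblast markers averaged -1.31, with 24 of 24 lower (adjusted p = 2.59e-10, and 0.956 with an estimated correlation). Without Sall4a-only replicate 1 that mean was -0.28 and the call was lost (adjusted p = 0.133), and without replicate 2 it was -2.35. Primitive endoderm genes averaged -0.52 (24 of 27 lower, adjusted p = 2.07e-06), imprinted genes -0.62 (17 of 21, 0.010), neuroectoderm genes -0.30 (19 of 22, 0.0049) and germ cell genes -0.20 (13 of 20, 0.0499), each with adjusted p = 0.956 with an estimated correlation. The imprinted gene mean was -0.015 without Sall4a-only replicate 1, where it did not pass, and -1.22 without replicate 2. Likewise the neuroectoderm mean was -0.099 without replicate 1, where it did not pass, and -0.51 without replicate 2, while the primitive endoderm mean was -0.27 without replicate 1 and passed. The germ cell mean was 0.036 without Sall4a-only replicate 2 and -0.44 without replicate 1, and the list also lost its call without control replicate 2 (-0.20), depleted replicate 2 (-0.17) or Sall4b-only replicate 1 (-0.20). Without depleted replicate 1 the trophoblast mean was 0.31 and did not pass.

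Among single genes, Dynap was at least 10.7-fold lower (adjusted p = 0.0564) and P2ry10b at least 6.76-fold lower (0.0624) in Sall4a-only than in depleted cells. Proser2 was 6.26-fold higher (0.0671), Dlx3 5.60-fold (0.0624) and the class I gene H2-Bl 2.40-fold higher (0.0624). By limma 0 genes passed, with 1096 at an unadjusted p under 0.05; 8 passed with a trended and robust prior and 6 with the mean of a gene's probe sets. Leaving out Sall4a-only replicate 2 gave 287 genes (42 higher and 245 lower), leaving out depleted replicate 2 gave 1, and leaving out any other array gave 0. The fit without Sall4a-only replicate 2 sets replicate 1 alone against the depleted arrays. Its leading genes included Rian, Mirg, Meg3 and Cav1, which lay lower on replicate 1 than on any other array. Its count therefore describes that array rather than the group. Groups did not overlap at 35.2% of genes, against 33.3% by chance.

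In Sall4b-only cells, which also carry an added cDNA, the trophoblast genes were lower than in depleted cells. They averaged -0.50 log2 (19 of 24 lower, adjusted p = 1.97e-05, and 0.956 with an estimated correlation), with Krt19 4.80-fold lower but Dlx3 2.62-fold higher, both past the threshold over the list alone. Fibroblast markers averaged -1.03 (21 of 24 lower, adjusted p = 1.34e-07, and 0.956 with an estimated correlation), with Col3a1 15.0-fold and Col5a2 4.74-fold lower. G2/M genes averaged 0.25 (24 of 24 higher, adjusted p = 0.0367) and imprinted genes -0.23 (14 of 21 lower, adjusted p = 0.0443), each with adjusted p = 0.956 with an estimated correlation. The G2/M mean was 0.12 without Sall4b-only replicate 1 and 0.38 without replicate 2, and the list did not pass without the former or without depleted replicate 1 (0.26) or 2 (0.24). The imprinted list did not pass without control replicate 2 (-0.23), depleted replicate 2 (-0.19), Sall4b-only replicate 1 (-0.18) or Sall4b-only replicate 2 (-0.29). Dynap was at least 8.93-fold lower, P2ry10b 6.44-fold lower and Sema3d 6.56-fold higher than in depleted cells (adjusted p = 0.0536 for each). Sorbs2 was 9.21-fold and Prl3a1 at least 6.58-fold lower (adjusted p = 0.0903).

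By limma 0 genes passed in Sall4b-only against depleted cells, with 1243 at an unadjusted p under 0.05 and 7 with a trended and robust prior. With only the 2 groups in the fit 61 passed, and without both Sall4a-only arrays 66 (12 higher and 54 lower). In the latter fit the small proline-rich gene Sprr2k fell by 4.21 log2 (adjusted p = 0.0075), Bmp7 rose at least 5.24-fold (0.0075) and Pdlim4 rose by 3.13 (0.0152). Leaving out either Sall4a-only array also gave 66, depleted replicate 2 gave 1, and any other array gave 0. Groups did not overlap at 56.7% of genes, against 33.3% by chance.

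Sall4a-only and Sall4b-only cells were compared directly, since per the labels both carry the shRNA and differ by the isoform of the added cDNA, whose expression the Sall4 probe sets did not show. Trophoblast genes averaged 0.96 log2 higher with Sall4a than with Sall4b, with 20 of 24 higher (camera adjusted p = 4.19e-14, and 0.956 with an estimated correlation, where the raw p was 0.0077). Over the list alone 11 members passed and all were higher with Sall4a, while 0 passed over all genes. The variance is shared by all groups, and the Sall4a-only pair spread most (SD of the replicate difference 0.62 log2). Errors in comparisons with Sall4a-only cells may therefore be understated. Counts over a list alone were not repeated with only the 2 groups in the fit. Krt7 was 3.46 log2 higher (12.6 ± 0.81 against 9.12 ± 0.19 log2, SD, n = 2), Hand1 8.35-fold (10.3 ± 0.97 against 7.25 ± 0.29), Krt19 7.10-fold (13.1 ± 0.68 against 10.3 ± 0.40) and Esx1 2.50-fold (8.90 ± 0.0039 against 7.58 ± 0.21). Bmp8b, Cdx2, Wnt7b, Plet1, Krt8, Dlx3 and Krt18 were between 3.04-fold and 1.504-fold higher. The list mean lay between 0.87 and 1.05 whichever array was left out.

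Pluripotency genes averaged -0.25 with Sall4a against Sall4b (38 of 40 lower, adjusted p = 8.98e-04, and 0.956 with an estimated correlation), with Klf2 at -0.44 (SE 0.16) and Zscan10 at -0.63 (SE 0.23). G2/M genes averaged -0.29, all 24 lower (adjusted p = 2.81e-04, and 0.956 with an estimated correlation). Primitive endoderm genes averaged -0.46 (24 of 27 lower, adjusted p = 0.0037, and 0.956 with an estimated correlation), with Hnf4a 3.75-fold lower and past the threshold over the list alone. Germ cell genes averaged -0.27 (18 of 20 lower, adjusted p = 0.0499) and Polycomb complex genes -0.14 (15 of 19 lower, adjusted p = 0.0368), each with adjusted p = 0.956 with an estimated correlation. Interferon response genes averaged 0.29 (15 of 21 higher, adjusted p = 0.0118, and 0.956 with an estimated correlation), among them Cxcl10 (1.46, SE 0.44) and the class I gene H2-K1 (1.13, SE 0.34). Fibroblast markers averaged -0.29 (16 of 24 lower) and did not pass (adjusted p = 0.436).

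These smaller list differences between Sall4a-only and Sall4b-only cells hung on single arrays. Without Sall4a-only replicate 2 the means were -0.075 for pluripotency, -0.089 for G2/M, -0.035 for germ cell and -0.063 for Polycomb complex genes, and none passed; without replicate 1 they were -0.42, -0.49, -0.51 and -0.22. The primitive endoderm mean was -0.21 without Sall4a-only replicate 1 and -0.24 without Sall4b-only replicate 1, neither of which passed, and -0.71 without Sall4a-only replicate 2. Interferon response genes averaged 0.27 and 0.22 without the same replicate 1 arrays and did not pass. Calls were also lost without Sall4b-only replicate 1 for G2/M (-0.16) and Polycomb complex genes (-0.12), without control replicate 2 for Polycomb complex genes (-0.14), and without Sall4b-only replicate 2 (-0.20) or either control array (-0.27) for germ cell genes.

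Sema3d was 6.32-fold lower with Sall4a than with Sall4b (5.90 ± 0.11 against 8.56 ± 0.43 log2; adjusted p = 0.101). H2-Bl was 2.40-fold and the protease gene Tmprss2 2.46-fold higher (adjusted p = 0.101), and Septin4 7.35-fold and the myelin gene Mbp 3.20-fold higher (adjusted p = 0.215). By limma 0 genes passed, with 820 at an unadjusted p under 0.05; 0 passed with a trended and robust prior and 0 with only the 2 groups. Without Sall4a-only replicate 1 the count was 2 (Hand1 and Gzme, both higher), without Sall4a-only replicate 2 it was 47 (10 higher and 37 lower), and without any other array it was 0. The fit without Sall4a-only replicate 2 again rests on replicate 1 alone. Its leading genes included Rian, Meg3, Mirg and Cd44, which lay lower on that array than on any other. Groups did not overlap at 34.1% of genes, against 33.3% by chance.

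**Figure D3:**
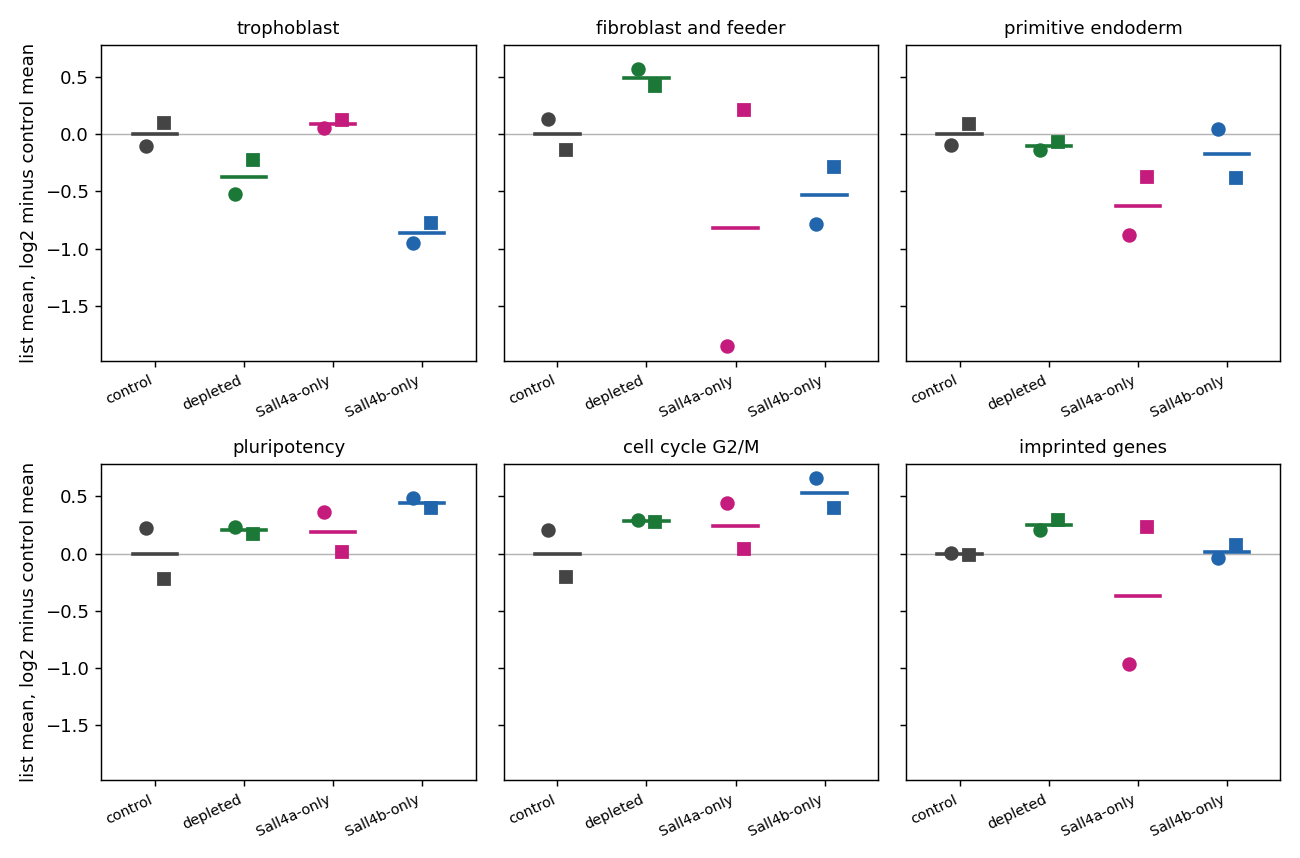
Mean log2 difference from the control mean over the measured genes of 6 lists on each array, by group; circles are replicate 1, squares are replicate 2 and bars are group means. Trophoblast means are lowest on both Sall4b-only arrays (-0.95 and -0.78), and the fibroblast mean is lowest on Sall4a-only replicate 1 (-1.86).

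Whether either isoform returned the genes that respond to depletion could not be asked of genes past the threshold, since 0 passed. A set chosen after seeing the data, at an unadjusted p under 0.01, held 166 genes higher and 116 lower in depleted cells. Chosen by their depleted values, these genes have large depleted medians by selection, and values of other groups against the same controls come out nearer 0 without any restoration. Genes of the higher set had a median difference from control of 0.84 in depleted, 0.485 in Sall4a-only and 0.66 in Sall4b-only cells, and a median of -0.14 between Sall4a-only and Sall4b-only cells (camera p = 2.07e-05, and p = 0.0262 with an estimated correlation). For the lower set the medians were -0.66, -0.35 and -0.54, and the difference was 0.17 (camera p = 1.12e-11, and p = 0.0270 with an estimated correlation). Both sets were chosen with a variance shared by all arrays, so the add-back arrays helped choose the genes they then test. With only the 2 groups compared in the fit, the higher set's median was -0.12 (camera p = 0.0238, and p = 0.595 with an estimated correlation). The lower set's median there was 0.13 (camera p = 1.65e-05, and p = 0.0274 with an estimated correlation). Without Sall4a-only replicate 1 the higher set's difference between the add-back groups was 0.12, and without control replicate 2 the lower set's was -0.022.

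Calls in the add-back comparisons against control overlapped at 1 gene, Mmp12. Independent lists give 7.13e-05 and simulated unchanged groups 0 on average, but so few genes passed that these values do not weigh the overlap. Fold changes of Sall4a-only and Sall4b-only cells against control had a covariance over genes of 0.110, against 0.0450 in 100 simulations of unchanged groups, a difference of 0.0648; the correlation was 0.690 against 0.501 simulated. For depleted and Sall4b-only cells the covariance was 0.0719 against 0.0449, with a correlation of 0.503 against 0.501, and for depleted and Sall4a-only cells 0.0464 against 0.0449, with a correlation of 0.384, below the simulated 0.4996. For the add-back groups against the depleted cells it was 0.1001 against 0.0449, with a correlation of 0.660 against 0.5002. Genes are not independent replicates, and with 2 control arrays the controls cannot be split, so part of any excess may come from the shared arrays. The simulations also gave all groups the same spread per gene. In the data the SD of the replicate difference was 0.27 log2 in depleted, 0.41 in control and 0.62 in Sall4a-only cells. Simulated values are therefore not matched to these groups, and no excess or shortfall against them is weighed here.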

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

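The tests that weigh explanations here were chosen after the result was seen; the list tests were planned. What drew attention was a difference between the effects of Sall4a and Sall4b add-back, both in cells with the shRNA, tested directly by camera for 24 lists, of which 7 passed. None of the 7 passed with a correlation estimated per list (adjusted p = 0.956) or by fry. In mean log2, Sall4a minus Sall4b, the differences were 0.96 for trophoblast genes, 0.29 for interferon response genes, -0.25 for pluripotency genes, -0.46 for primitive endoderm genes, -0.27 for germ cell genes, -0.29 for G2/M genes and -0.14 for Polycomb complex genes. Only the trophoblast list passed whichever array was left out. Without Sall4a-only replicate 2 the means were -0.075 for pluripotency, -0.035 for germ cell, -0.089 for G2/M and -0.063 for Polycomb complex genes, and without Sall4a-only replicate 1 they were -0.21 for primitive endoderm and 0.27 for interferon response genes; none of these passed.

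The trophoblast difference was weighed further because it held whichever array was left out. Without Sall4a-only replicate 1, the array that stood apart, the mean difference was 0.99, which argues against that array as its only source. The Sall4a-only arrays lay 2.07 log2 apart in the mean of fibroblast markers but 0.074 apart in that of trophoblast genes. For the list mean, this argues against the share of fibroblast-like cells as the source. Members that move in opposite ways cancel in such a mean, and Hand1, Krt7 and Krt19 differed more between these arrays. For single members that explanation therefore stays open. An effect of the isoform present, which the design names, stays open as a hypothesis, untested here apart from the group. Differences between the cultures or virus preparations of the groups, and a weak or failed add-back of either isoform, which the Sall4 probe sets did not show, also stay open.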

How the results depend on the processing

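The fit without both Sall4a-only arrays, the crossed block, fry and the depletion-responsive set were chosen after the results were seen; the other alternatives were planned. Except where a construction is named, the cause of a difference was not tested. Gene counts follow the order depleted, Sall4a-only and Sall4b-only against control, Sall4a-only and Sall4b-only against depleted, and Sall4a-only against Sall4b-only; they were 0, 1, 1, 0, 0 and 0. With a trended and robust prior they were 2, 7, 17, 8, 7 and 0, and 6 calls were shared between the add-back groups against control, where 1 was. With only the 2 groups compared they were 0, 0, 14, 0, 61 and 0. Presence on all 8 arrays removed Mmp12, which left 0 calls and 0 shared. Mean values over a gene's probe sets gave 2 for Sall4a-only against control and 6 against depleted, and cyclic loess gave 3 for Sall4b-only against control. Without both Sall4a-only arrays Sall4b-only cells gave 121 against control and 66 against depleted. No detection filter, every probe set and the 1.5-fold threshold left all 6 counts as they were, and the other deposited table holds the same values and tests nothing.

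The labels do not say that replicate numbers pair the arrays. Differences between replicates correlated at 0.568 between control and depleted and at -0.117 to 0.196 between the other groups, so the numbers may mark something shared in the former. With the replicate block, a single shift per gene common to all 4 groups, the counts were 0, 0, 2, 0, 0 and 0 and 0 calls were shared. A block for control and depleted cells alone was not fitted, so that pairing stays untested. Of the 28 called lists other than the list with the smallest p in each comparison, 1 lost its call with the block. The crossed block for Sall4b-only against depleted, whose numbers correlated at -0.117, gave 0, with 1257 genes at an unadjusted p under 0.05.

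With 1 array left out at a time the gene counts ran from 0 to 1, 0 to 110, 0 to 121, 0 to 287, 0 to 66 and 0 to 47, and shared calls from 0 to 36. Lists passing were 5, 5, 7, 6, 4 and 7, and with 1 array left out ran from 0 to 8, 2 to 8, 4 to 8, 5 to 7, 2 to 7 and 4 to 8. They were 8 for depleted against control and 7 for Sall4b-only against depleted with only the 2 groups or without both Sall4a-only arrays, and 3 for Sall4a-only against depleted with presence on all 8 arrays. With an estimated correlation and by fry 0 lists passed. The leading list of each comparison lost its call there; these settings do not recompute the mean, which was 0.28 (G2/M; fry adjusted p = 0.861), -0.63 (primitive endoderm; 0.579), -0.87 (trophoblast; 0.258), -1.31 (fibroblast; 0.695), -1.03 (fibroblast; 0.861) and 0.96 (trophoblast; 0.258). Leaving out 1 array, those means ran from 0.079 to 0.49, -0.88 to -0.37, -0.97 to -0.77, -2.35 to -0.28, -1.28 to -0.78 and 0.87 to 1.05. Lists that changed sign were pluripotency in depleted against control cells (-0.0198 without control replicate 2, 0.43 without control replicate 1), fibroblast in Sall4a-only against control cells (0.22 without Sall4a-only replicate 1, -1.86 without replicate 2) and germ cell in Sall4a-only against depleted cells (0.036 without Sall4a-only replicate 2, -0.44 without replicate 1). The median difference between add-backs ran from -0.29 to 0.12 for genes higher in depleted cells (0.12 without Sall4a-only replicate 1) and from -0.022 to 0.37 for genes lower there (-0.022 without control replicate 2).

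Of 517 recomputed results of the 28 other called lists, 395 kept their call, 119 lost it and 3 changed sign. Of 7852 recomputed values of named genes, 128 newly passed, 13 no longer passed and 30 changed sign; since only Mmp12 passed with the settings of the report, the side of the threshold says little about how stable the others are. The log2 difference of the brighter Sall4 probe set in depleted against control cells ran from -0.53 to -0.40 and of the dimmer from -1.34 to -1.16. The median difference over all genes was 0.061 and 0.065 for Sall4b-only against control and depleted, and 0.044 and 0.035 after cyclic loess, which moved no gene's difference by more than 0.047. Probe sets called absent in a group, such as Mmp12 in both add-back groups, have only bounds, and the number of arrays limits the rest.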

Other observations

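All tests of explanations in this part were chosen after the results were seen; the gene lists and their tests were planned, and fry and the fit without the Sall4a-only arrays were not. Lists not yet described did not pass in Sall4b-only against control cells. Members past the threshold over the list alone are named where a list held any, but none of them passed over all genes. Of 19 FGF/ERK target genes 11 were higher and 8 lower, and the mean (-0.083) and median (0.20) differed in sign (camera adjusted p = 0.986). The higher members past the threshold over the list alone were Spry4 (0.92, SE 0.26), Il17rd (0.83, SE 0.15), Spry1 (0.70, SE 0.22), Spred1 (0.45, SE 0.11) and Spred2 (0.42, SE 0.11), and the lower were Fos (-1.24, SE 0.25), Fosl1 (-1.001, SE 0.28) and Dusp5 (-0.88, SE 0.20). Fibroblast markers moved beside them, with a mean of -0.53. Of LIF/STAT3 targets (mean -0.049, adjusted p = 0.385), Gbx2 and Socs3 were higher and Pim1 lower; Sall3 of the SALL family was 2.14-fold higher (list mean 0.49, adjusted p = 0.259), and likewise 2.05-fold in depleted and 1.84-fold in Sall4a-only cells.

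Hox genes averaged -0.13 (adjusted p = 0.190), with Hoxd9 1.97-fold and Hoxb13 2.18-fold lower and Hoxa5 at least 1.44-fold higher. Epiblast genes averaged 0.31 (0.270), with Enpp3 3.10-fold higher and Sox4 2.20-fold lower, and mesoderm and primitive streak genes 0.30 (0.558), with Mef2c at least 2.84-fold higher. Glycolysis and hypoxia genes averaged -0.12 (0.242), with Pkm 1.89-fold lower (1.92-fold in depleted and 1.71-fold in Sall4a-only cells), BMP targets 0.077 (0.868), with Bambi 1.48-fold higher, and Wnt targets 0.52 (0.247). Cholesterol synthesis genes averaged 0.028 (0.985) and NuRD complex genes 0.032 (0.969), though camera's direction was down for both; Idi1 was 1.58-fold higher and Sc5d 1.60-fold lower. Neuroectoderm genes averaged -0.0068 with a median of 0.17 (0.868), and Pax3 was 4.94-fold and Six3 1.66-fold lower. The 2-cell-like genes averaged 0.66, with 10 of 10 higher (adjusted p = 0.247).

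Sall4a-only replicate 1 held a set of transcripts at far lower levels than every other array, found after the values were seen. On it 23 genes lay over 2 log2 below all 7 other arrays, against 0 such genes on each of the others. The RNAs Rian, Meg3 and Mirg, transcribed from the imprinted Dlk1-Dio3 region, stood at 6.44, 6.18 and 4.68 log2 there, against 12.2 to 13.0, 10.6 to 11.9 and 9.18 to 10.9 elsewhere. All probe sets agreed, 11 of 11 for Meg3, 4 of 4 for Rian and 2 of 2 for Mirg being lowest on that array. Stromal genes were low on it too: Col1a2 at 7.02 against at least 10.2 elsewhere, Inhba at 4.77 against 8.33, Col8a1 at 6.42 against 9.49 and Cav1 at 6.68 against 9.12.

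The Sall4a cDNA, which both arrays of the group carry per the labels, is argued against as the source of the low Rian, Meg3 and Mirg, since on Sall4a-only replicate 2 they lay 0.29 log2 above the control mean; how much Sall4a each culture made was not measured. Fewer fibroblast-like cells in that culture may account for the stromal genes, but the test left it open: of 24 further fibroblast markers 18 were measured and 9 (50%, exact 95% interval 26.0 to 74.0%) were lowest there, against 12.5% by chance. The value sat on the bound of 50% set against this explanation, and the demand that the interval clear that bound was added after the share was seen; Col8a1 and Sparc had also been seen earlier, and without them the share was 7 of 16 (43.8%, 19.8 to 70.1%). Both intervals treat markers of 1 culture as independent trials, although genes of the fibroblast list had an estimated correlation of 0.87. That array was also singled out for its low values, so the 12.5% is no fair reference for it. The median drop of the 18 markers there was -0.47 log2. For Rian, Meg3 and Mirg the same explanation also stays open, since between Sall4b-only and control cells they lay 1.44 SD from the 5 fibroblast genes that fell most on that array (-0.086 against a mean of -1.85), and loss of imprinting in that culture was not tested.

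Few genes passed in Sall4b-only against control cells although many differed in size. A candidate explanation is the wide spread of the Sall4a-only pair, which enters the shared variance: without that pair 121 genes passed. The number of groups in the fit stays open: without the depleted pair 0 passed, but that pair was the tightest (SD 0.27), so its loss raises the shared variance and decides nothing. The 121 held the 1 gene called with all 8 arrays, Mmp12. Which of these genes would pass in a larger set of cultures stays open.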
